A study of Mus musculus with 6 samples.

How the data were processed

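Liver RNA of 6 female mice aged 8 weeks was measured on single-color expression arrays, 3 of strain SM/J and 3 of strain NZB/BinJ, with 1 array per mouse. The values used are those of the deposited series table, with 1 column per mouse, and every column was matched to a mouse by its sample name, so that 0 columns were left unmatched. Per the submitters' processing notes the values come from RMA, a method that corrects background, normalizes arrays and summarizes the probes of a probe set. The version and settings of RMA are not given in the sources used here. The unit is not named there either. The deposited values were read as log2 expression because their maximum, 14.9, lies under the log2 limit of a 16-bit scanner, 16, and above its natural log limit, 11.1. No further normalization was applied. The arrays had medians of 6.60 to 6.66 and standard deviations of 1.93 to 1.99, with the SM arrays slightly wider. RMA compresses small differences near background and saturation limits the brightest probe sets, so differences at both ends of the scale can be understated. Sequence variants between the strains can weaken the binding of RNA to single probes, and they were not analysed here.

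Gene names came from a table that pairs the probe sets with the platform's annotation, and symbols were updated by Entrez ID through a RefSeq gene table of the mouse assembly GRCm38.p6. That table served for names and for the order of neighbouring genes only, and no coordinates are given, since the array table names no genome build. Of 45037 probe sets, 34945 were paired with 1 gene, 932 with several and 9160 with none. Of those with 1 gene, 34741 matched the RefSeq table and 204 kept the platform's symbol. A gene was represented by the probe set, among those paired with it alone, that had the highest mean over all 6 arrays, which gave 18193 genes. Of these, 9010 had several probe sets. Among the called genes, 891 had another probe set called in the same direction and 73 had one called in the opposite direction. Over all probe sets, 6659 passed the threshold (2745 higher and 3914 lower in NZB, and 13184 at an unadjusted p under 0.05), 744 of them with no gene and 201 with several. The probe sets passing numbered 4117, 4413 and 3741 without SM replicate 2, NZB replicate 2 and NZB replicate 3.

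The strains were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with trend and robust estimation off), two-sided, with Benjamini-Hochberg adjustment over all 18193 genes and a threshold of 0.05. Differences are NZB minus SM. With 3 mice against 3, an exact permutation test of a single gene cannot go below p = 0.1, so no such test was used. The threshold for a large difference was 2-fold. Folds are 2 to the power of the difference in log2 expression.

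Before the data were examined, 38 gene lists were fixed from general knowledge of liver biology, covering metabolic pathways, sex-biased genes, stress and clock genes, and markers of other cell types that liver tissue can hold. A list was tested where at least 5 members were measured, which held for 37. Members not measured through a probe set of their own were not analysed here. Each list was tested with camera, which asks whether its genes are shifted one way relative to all other genes, with a preset inter-gene correlation of 0.01 and again with the correlation estimated from the residuals. It was also tested with a one-sided Fisher's exact test of whether its share of called genes exceeded that of all genes tested. The p-values of each test were adjusted over the 37 lists. Camera called 20 lists as shifted with the preset correlation and Fisher's test called 18. With the estimated correlation camera called 0 lists, and 6 had an unadjusted p under 0.05. The size of the correlation alone does not account for this. For B and plasma cell markers it was estimated at 0.003, under the preset, yet the unadjusted camera p went from 8.7e-07 to 0.0069. With the estimated correlation camera also takes its degrees of freedom from the residuals of the 6 arrays. With the preset correlation it takes them from the number of genes tested. A list can therefore lose its call without correlated genes. Counts adjusted over the list alone use only the p-values of that list's members.

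The genes named in the text follow a rule fixed at the same time. It takes the 8 largest differences in each direction among genes past the threshold whose arrays did not overlap between strains, leaving out clone and predicted names. From each list with at least 3 members past the threshold it takes up to 2 members per direction with the largest differences. It adds the candidates for HDL cholesterol, 10 genes of which 7 were measured through a probe set of their own and the others were not analysed here. The rule names 113 genes. A further 32 were chosen after their values were seen, to complete counts of 5 or fewer, and Xist, the Y-linked genes and the genes that escape X inactivation were read to check the sex given in the labels.

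The alternatives were the replicate number as a block, trended and robust variances, array medians aligned, quantile normalization, leaving out the dimmer probe sets (mean at or below the median of all probe sets), array weights, the mean over a gene's probe sets, leaving out probe sets whose identifiers mark possible cross-hybridization, and leaving out each array in turn. All 10 splits of the 6 arrays into groups of 3 were also run. The scripts were tested on simulated data with the real genes' means and spreads: with 50 genes changed at each size among 18193, 70% were called at a log2 difference of 0.5, 94% at 1 and 100% at 2 and at 4, and 6 unchanged genes were called. Far fewer genes were changed there than the 3827 called in the real data. The Benjamini-Hochberg cut depends on that share, so these rates check the scripts and do not carry over to the real comparison. In the same simulation a list of 20 genes shifted by 0.5 was called with the preset and the estimated correlation (adjusted p = 3.2e-41 and 0.000245), and an unshifted list was not (0.296 and 0.336). Noise was drawn independently for each gene, so these lists held no inter-gene correlation. The result does not show how either setting does with correlated genes, such as those of cholesterol synthesis (estimated correlation 0.61). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.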

Results

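Liver RNA was profiled on expression arrays in 6 untreated female mice aged 8 weeks, with 1 array per mouse. Of these, 3 mice came from the inbred strain SM/J (SM) and 3 from the inbred strain NZB/BinJ (NZB), and the labels call the mice of a strain biological replicates. The animals ate chow after weaning at 3 weeks, went without food for 4 hours before dissection, and had their livers rinsed by perfusion with 50 mL of saline. Each array gave a log2 expression value for 45037 probe sets, and its median lay between 6.60 and 6.66. Across probe sets, arrays of the same strain correlated at 0.995 to 0.997 and arrays of different strains at 0.985 to 0.987 (Pearson's r across probe sets, which are not independent replicates). The first principal component held 69% of the variance and separated the strains. The arrays of SM replicates 1, 2 and 3 read 12.8, 7.32 and 12.9 for Xist, the RNA made from an inactive X chromosome, and the 3 NZB arrays read 12.7, 12.6 and 12.6. SM replicate 2 therefore stood apart from the other 5 arrays in this gene. The number of arrays, 3 per strain, limits the precision of every value.

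The design implies a single comparison, which asks how the liver transcriptome of adult females differs between NZB and SM mice. Differences are given as NZB minus SM on the log2 scale with the standard error of the limma fit, and a gene is called higher or lower in NZB where its Benjamini-Hochberg adjusted p was under 0.05. Of 18193 genes tested, 1541 were higher in NZB and 2286 were lower, 3827 in all. A difference of at least 2-fold was found for 280 of them, 145 higher and 135 lower, and the median size of a called difference was 0.37. The 3 arrays of one strain lay wholly above those of the other for 39.4% of all genes, where chance gives 10%, and for 3800 of the called genes. The called genes numbered 2371 (873 higher, 1498 lower) without SM replicate 2 and 2398 (900 higher, 1498 lower) without NZB replicate 3, and 1012 were higher without NZB replicate 2. The share of calls that were higher in NZB was 40.3% as deposited, 30.3% with the array medians aligned and 47.5% after quantile normalization.

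Among the genes that were lower in NZB, the oxysterol hydroxylase Cyp39a1 had a log2 difference of -5.92 (SE 0.12, adjusted p = 1.9e-08). Its level was 10.9 ± 0.21 in SM and 4.99 ± 0.20 in NZB (SD, n = 3 each). Background is taken here as 5.67, the highest reading of a probe set for Y-linked genes, whose RNA females lack, and against it Cyp39a1 was at least 37.7-fold lower in NZB. The steroid 17α-hydroxylase Cyp17a1 was 44.3-fold lower in NZB (-5.47, SE 0.12, adjusted p = 1.9e-08), at 12.7 ± 0.040 in SM and 7.27 ± 0.27 in NZB. Wfdc21, which encodes a small protein of the whey acidic protein family, was 36.5-fold lower (-5.19, SE 0.15, adjusted p = 1.4e-07), and Nnmt, the nicotinamide N-methyltransferase, was 23.1-fold lower (-4.53, SE 0.24, adjusted p = 5.3e-06). The others in this group were the sulfotransferase Sult2a2 (-4.25, SE 0.92, adjusted p = 0.0111), Gdpd3 (-3.45, SE 0.23), the peptidase Mme (-3.39, SE 0.17, at least 5.38-fold lower against background) and the cytochrome P450 Cyp2c23 (-3.23, SE 0.080). Sult2a2 read 10.7, 10.6 and 6.43 in the 3 NZB arrays against a mean of 13.5 ± 0.032 in SM, and its call ended with trended and robust variances (adjusted p = 0.115, range over all settings 7.3e-07 to 0.115). Mme has another probe set with a smaller difference. It became the brighter one without SM replicate 1, 2 or 3, and the differences were then -1.30, -1.45 and -1.37.

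Among the genes that were higher in NZB, the short-chain dehydrogenase Sdr9c7 had a log2 difference of 4.55 (SE 0.21, adjusted p = 2.2e-06). It read 5.59 in SM, under background, and was at least 22.2-fold higher in NZB against it. A group of immunoglobulin genes followed. Ighm, the constant region of the IgM heavy chain, was 20.3-fold higher (4.35, SE 0.21, adjusted p = 3.4e-06), Jchain, which joins IgM into polymers, was 19.5-fold higher (4.28, SE 0.30), and the kappa light chain gene Igkv8-30 was 11.7-fold higher (3.55, SE 0.21). Hsd3b5, a hydroxysteroid dehydrogenase known to be made mainly in male mouse liver, was 19.9-fold higher (4.31, SE 0.30, adjusted p = 2.5e-05). The major urinary protein gene Mup10 (3.58, SE 0.20), the steroid reductase Akr1c18 (3.47, SE 0.13) and the plasma protein gene Orm1 (2.94, SE 0.34) made up the rest. The immunoglobulin, Mup, Orm, Sult and Cyp2c genes have near-identical copies that a probe set can read as well, so the member behind these values is uncertain. Of the 11 probe sets of Ighm, 3 others were higher in NZB and 7 did not pass the test, and the mean over its probe sets differed by 0.94.

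**Figure D1:**
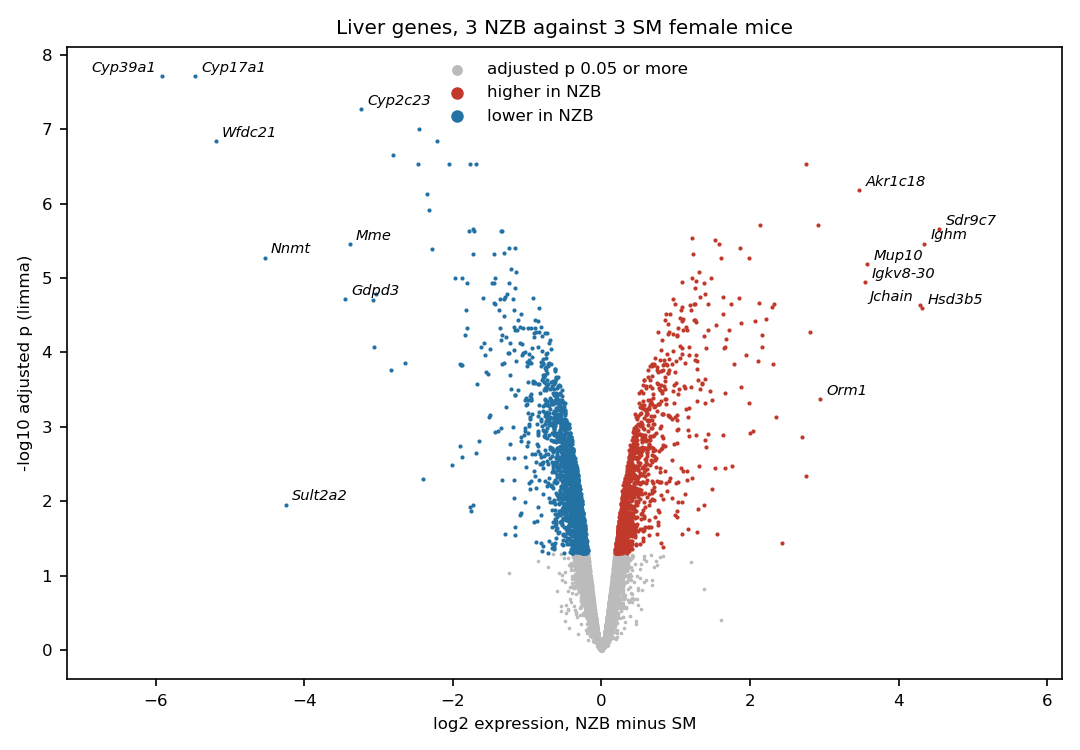
Each point is 1 of 18193 genes, placed by its log2 difference in expression (NZB minus SM, 3 mice each) and by -log10 of its limma adjusted p. The 1541 genes higher in NZB are red, the 2286 lower are blue, and the named genes run from Cyp39a1 at -5.92 to Sdr9c7 at 4.55.

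Crosses between these strains have been used to map genes for HDL cholesterol, and 7 of the 10 candidate genes fixed beforehand for that trait were tested. The main HDL apolipoproteins did not differ past the threshold: Apoa1 differed by 0.018 (SE 0.062, adjusted p = 0.870) and Apoa2 by 0.035 (SE 0.060, adjusted p = 0.723). Both lie near the top of the scale at 14.7 and 14.8 in SM, where arrays can saturate, and quantile normalization turned both differences slightly negative. The HDL receptor gene Scarb1 was 2.14-fold lower in NZB (-1.09, SE 0.093, adjusted p = 7.6e-05), at 12.3 ± 0.17 in SM and 11.2 ± 0.10 in NZB. The phospholipid transfer protein gene Pltp was 1.41-fold higher (0.50, SE 0.084, adjusted p = 0.00325), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 3.21-fold lower (-1.68, SE 0.26, adjusted p = 0.00226). The cholesterol exporter gene Abca1 differed by -0.26 (SE 0.092, adjusted p = 0.0717) and Lcat, which esterifies HDL cholesterol, by -0.067 (SE 0.076, adjusted p = 0.580). Abca1 passed the threshold without SM replicate 1 and without NZB replicate 2 (adjusted p = 0.0490 and 0.0459).

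Of 25 measured HDL and lipoprotein genes, 6 were higher in NZB, 5 were lower and 14 did not pass the test (6 and 7 adjusted over the list alone). Lipoprotein lipase, Lpl, was 4.36-fold higher (2.12, SE 0.14, adjusted p = 2.1e-05), while the endothelial lipase gene Lipg was 2.72-fold lower (-1.45, SE 0.098, adjusted p = 2.2e-05). The members lower in NZB were Lipg, Scarb1, Angptl4, Vldlr and Apoa5. The list as a whole was not shifted (camera adjusted p = 0.588, and adjusted p = 0.815 with an estimated correlation). Its share of called genes exceeded that of all genes (one-sided Fisher's exact test, adjusted p = 0.0169). That share no longer passed without SM replicate 3 (0.0580), NZB replicate 3 (0.0674), dim probe sets (0.0884) or probe sets marked for cross-hybridization (0.0990). The lower members numbered 3, 3 and 2 without SM replicate 2, NZB replicate 2 and NZB replicate 3. Single arrays left out ended the calls of Angptl4 (adjusted p = 0.0867 to 0.112 without SM replicate 2 or 3 or NZB replicate 2 or 3), Vldlr (0.0690 to 0.0851 without SM replicate 2 or NZB replicate 2 or 3) and Apoa5 (0.0593 to 0.0706 without NZB replicate 2 or 3). Other settings ended those of Angptl4 (0.0552 to 0.439 in 3 settings, with a difference of -0.092 without probe sets marked for cross-hybridization) and Vldlr (0.0878 with the mean of its probe sets and 0.446 without the marked ones, where 3 members were lower). Besides these, the replicate block ended the call of Angptl4 (limma adjusted p = 0.0523).

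All but 1 of the cholesterol synthesis genes past the threshold were higher in NZB. Of 20 measured members, 10 were higher, 1 was lower and 9 did not pass the test (11 and 1 adjusted over the list alone), with a median difference of 0.39 (camera adjusted p = 0.000193, and adjusted p = 0.478 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, was 3.87-fold higher (1.95, SE 0.18, adjusted p = 0.000108), and Fdps, which makes farnesyl diphosphate, was 2.60-fold higher (1.38, SE 0.30, adjusted p = 0.0113). The exception was the ketoreductase gene Hsd17b7 (-0.28, SE 0.065, adjusted p = 0.0159). The number of higher members fell to 5 without SM replicate 2, to 6 without NZB replicate 1 or NZB replicate 2, to 4 without NZB replicate 3, and to 6 with trended and robust variances. The call of Hsd17b7 ended without NZB replicate 2 (adjusted p = 0.0521) and after quantile normalization (0.1004). That of Fdps ended with trended and robust variances (adjusted p = 0.0924, range over all settings 0.00136 to 0.0924), and Fdps differed by 0.72 with the mean of its probe sets.

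Of 22 measured genes of bile acid synthesis and transport, 11 were lower in NZB, with 4 higher and 7 not past the test (the same counts adjusted over the list alone). The median difference was -0.23 (camera adjusted p = 0.00277, and adjusted p = 0.260 with an estimated correlation). Cyp39a1 and Cyp7a1, which both add a 7α-hydroxyl group to sterols, differed most among the lower members. A further 7α-hydroxylase gene, Cyp7b1, went the other way and was 3.16-fold higher (1.66, SE 0.18, adjusted p = 0.000354), as was the organic anion transporter gene Slco1a1 by 2.32-fold (1.21, SE 0.22, adjusted p = 0.00489). The remaining higher members were the canalicular exporter gene Abcc2 and Hsd3b7.

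Genes of fatty acid oxidation and targets of the nuclear receptor PPAR alpha were lower in NZB in 12 of 23 cases, with 1 higher and 10 not past the test (14 and 1 adjusted over the list alone). The fatty acid transporter gene Cd36 was 3.50-fold lower (-1.81, SE 0.11, adjusted p = 1.2e-05) and the pantetheinase gene Vnn1 was 2.24-fold lower (-1.16, SE 0.31, adjusted p = 0.0281). Fabp1, the liver fatty acid binding protein, was 1.16-fold higher (0.21, SE 0.059, adjusted p = 0.0304). The list's median difference was -0.30 (camera adjusted p = 1.5e-05, and adjusted p = 0.330 with an estimated correlation). Of 20 measured genes of fatty acid and triglyceride synthesis, 7 were lower, 1 was higher and 12 did not pass (9 and 1 adjusted over the list alone). Thrsp, a thyroid hormone responsive gene of lipid synthesis, was 3.12-fold lower (-1.64, SE 0.24, adjusted p = 0.00156), the elongase gene Elovl6 was 1.85-fold lower (-0.89, SE 0.25, adjusted p = 0.0355), and the elongase gene Elovl5 was 1.20-fold higher (0.27, SE 0.071, adjusted p = 0.0262). This list's median was -0.16 (camera adjusted p = 0.0269, and adjusted p = 0.556 with an estimated correlation), and its call ended without SM replicate 1 (0.130), without NZB replicate 3 (0.0554) and under 3 other settings (0.0532 to 0.116). Its share of called genes was not raised (Fisher's exact test, adjusted p = 0.0744). Without SM replicate 2 or NZB replicate 2, the lower oxidation genes numbered 6 and 5, and the median of the synthesis list was -0.11 without NZB replicate 1. That median was -0.097 after quantile normalization and -0.11 without probe sets marked for cross-hybridization. Without SM replicate 1, 2 synthesis genes were higher. Single arrays left out also ended the calls of Vnn1 (adjusted p = 0.0613 to 0.0981 without SM replicate 2 or NZB replicate 2 or 3, with a difference of -0.72 without SM replicate 3) and Fabp1 (0.0590 to 0.102 without any array but NZB replicate 2). They also ended those of Elovl6 (0.05004 to 0.132 without SM replicate 1 or 2 or NZB replicate 1 or 3, with a difference of -0.57 without SM replicate 1) and Elovl5 (0.0679 to 0.101 without SM replicate 2 or NZB replicate 1 or 3). Other settings ended those of Vnn1 (0.0524 to 0.147 in 2 settings), Fabp1 (0.0516 to 0.0810 in 3), Elovl6 (0.0602 to 0.152 in 3) and Elovl5 (0.0504 in 1). Besides these, the replicate block ended the call of Fabp1 (limma adjusted p = 0.0615).

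Genes of gluconeogenesis and fasting were lower in NZB in 8 of 13 cases, with none higher and 5 not past the test (10 lower adjusted over the list alone). Igfbp1, a fasting-induced binding protein of insulin-like growth factors, was 3.31-fold lower (-1.73, SE 0.38, adjusted p = 0.0112), and the alanine aminotransferase gene Gpt2 was 2.19-fold lower (-1.13, SE 0.084, adjusted p = 3.7e-05). Glucocorticoid targets were lower in 7 of 12 cases with none higher (8 lower adjusted over the list alone). Among these, the clock gene Per1 was 3.07-fold lower (-1.62, SE 0.14, adjusted p = 8.3e-05) and the receptor cochaperone gene Fkbp5 was 2.43-fold lower (-1.28, SE 0.15, adjusted p = 0.000545). Of 17 measured genes of the urea cycle and amino acid catabolism, 6 were lower and none was higher (8 lower and 1 higher adjusted over the list alone). The proline dehydrogenase gene Prodh (-0.74, SE 0.076, adjusted p = 0.000234) and the tyrosine aminotransferase gene Tat (-0.73, SE 0.090, adjusted p = 0.000625) differed by 1.67-fold and 1.66-fold. Tat belongs to all 3 of these lists, and Per1 also to the clock list. The median differences were -0.39, -0.45 and -0.16 (camera adjusted p = 2.1e-05, 0.000116 and 0.000661, and adjusted p = 0.233, 0.261 and 0.478 with an estimated correlation). The urea cycle list's share of called genes was not raised (Fisher's exact test, adjusted p = 0.197). Without SM replicate 2, the lower genes of the gluconeogenesis and glucocorticoid lists numbered 4 each, and the call of Igfbp1 ended (adjusted p = 0.0519). It also ended with trended and robust variances (0.103, range over all settings 0.00243 to 0.103). Of the urea cycle list 1 gene was higher without SM replicate 1 and with array weights, and of the glucocorticoid targets 1, Mt1, without probe sets marked for cross-hybridization. With the mean of its probe sets Fkbp5 differed by -0.75.

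Genes known to differ between the sexes in mouse liver went in opposite directions in these females. Of 11 measured male-biased genes, 8 were higher in NZB and none was lower, with a median difference of 1.03. Of 10 measured female-biased genes 6 were lower and 1 was higher, with a median of -0.70 (the same counts adjusted over each list alone). After Hsd3b5, the elongase gene Elovl3 differed most among the male-biased genes and was 3.96-fold higher (1.99, SE 0.23, adjusted p = 0.000483). After Cyp17a1, the sulfotransferase gene Sult3a1 differed most among the female-biased genes and was 3.67-fold lower (-1.88, SE 0.18, adjusted p = 0.000145). The female-biased gene that was higher, Hao2, encodes a hydroxyacid oxidase (1.17, SE 0.30, adjusted p = 0.0237). Both lists were shifted (camera adjusted p = 2.0e-05 for the male-biased and 0.000199 for the female-biased, and adjusted p = 0.330 for both with an estimated correlation). The 3 NZB arrays had Xist at 12.6 to 12.7, and SM replicate 2 had it at 7.32. The male-biased median was 0.57 without NZB replicate 3, and the call of Hao2 ended without any array but SM replicate 1 (adjusted p = 0.0565 to 0.0772) and with trended and robust variances (0.134). Of 3 measured major urinary protein genes, 1 was higher, Mup10, too few for a test of the list. Some sex-biased genes count in other lists too. Of the male-biased genes, Cyp7b1 and Slco1a1 are also in the bile acid list and Cyp2d9 in the cytochrome P450 list. Of the female-biased genes, Cyp3a16 is also in the cytochrome P450 list and Sult3a1 among the conjugating enzymes.

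Genes of xenobiotic metabolism differed in both directions. Of 26 measured cytochrome P450 genes of families 1 to 3, 5 were higher in NZB and 7 were lower, the same adjusted over the list alone. Cyp2c23, at 9.39-fold, and Cyp3a16, at 3.40-fold (-1.76, SE 0.39, adjusted p = 0.0119), differed most among the lower ones. The higher ones were Cyp2c55 (2.42, SE 0.70, adjusted p = 0.0367), Cyp2d9 (1.03, SE 0.19, adjusted p = 0.00554), Cyp2j5, Cyp2c54 and Cyp2c50. Of 31 measured conjugating enzymes, 11 were higher and 6 were lower (12 and 7 adjusted over the list alone). The sulfotransferase gene Sult5a1 was 3.67-fold higher (1.88, SE 0.14, adjusted p = 4.0e-05), the glutathione transferase gene Gstm6 was 3.45-fold higher (1.79, SE 0.17), and Gsta2 was 6.25-fold lower (-2.64, SE 0.25, adjusted p = 0.00014). Of 11 measured antioxidant targets of NRF2, both genes of the glutamate-cysteine ligase, Gclm (0.78, SE 0.084) and Gclc (0.54, SE 0.084), were higher, and Hmox1 (-0.89, SE 0.16), Me1 (-0.70, SE 0.15) and Txnrd1 were lower (4 higher and 3 lower adjusted over the list alone). None of the 3 lists was shifted one way (camera adjusted p = 0.270, 0.284 and 0.686, and adjusted p = 0.478, 0.809 and 0.815 with an estimated correlation). The shares of called genes were raised for the P450 and conjugating genes (Fisher's exact test, adjusted p = 0.00840 and 0.000274) but not for the NRF2 targets (0.103). Most genes of the Cyp2c, Cyp3a, Gstm, Sult and Ugt2b families have close relatives that a probe set can read, and their identity is uncertain. The higher P450 genes numbered 2 or 3 without any 1 of the 6 arrays, and the raised P450 share did not pass without SM replicate 3 (0.128) or under 4 other settings (0.05003 to 0.114). The NRF2 share passed without any 1 array but SM replicate 3 (0.00243 to 0.0369), and 4 NRF2 targets were higher without NZB replicate 1. Single arrays left out ended the calls of Cyp2c55 (adjusted p = 0.0560 to 0.105 without SM replicate 1, 2 or 3, with a difference of 1.39 without NZB replicate 2), Cyp2c54 (0.0681 to 0.114 without any array but SM replicate 2) and Cyp2c50 (0.0539 to 0.138 without any of the 6). Trended and robust variances ended that of Cyp3a16 (0.104, range over all settings 0.00888 to 0.104), and the mean of its probe sets that of Txnrd1 (-0.16, 0.261). Other settings also ended those of Cyp2c55 (0.0538 to 0.196 in 2 settings), Cyp2c54 (0.0539 to 0.0641 in 2) and Cyp2c50 (0.0905 in 1). Besides these, the replicate block ended the call of Cyp2c50 (limma adjusted p = 0.0814).

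**Figure D2:**
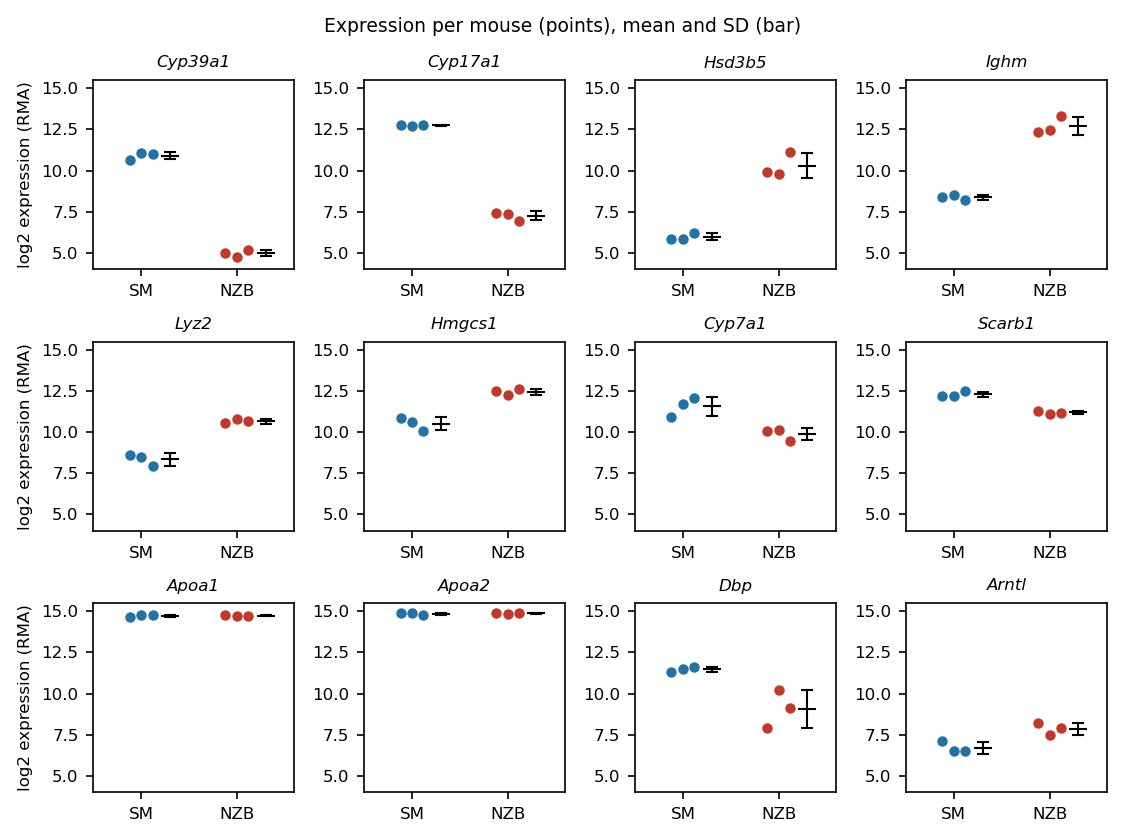
Points give log2 expression for each of the 3 SM (blue) and 3 NZB (red) mice in 12 genes, with the mean and SD as a bar. In Cyp39a1, Cyp17a1, Hsd3b5, Ighm, Lyz2, Hmgcs1, Cyp7a1, Scarb1, Dbp and Arntl the strains do not overlap, and in Apoa1 and Apoa2 all arrays lie near the top of the scale.

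Genes of the complement system were higher in NZB in 11 of 18 cases, with 2 lower and 5 not past the test (15 and 2 adjusted over the list alone). Those with the largest differences among the higher ones encode parts of the membrane attack complex: C8b was 2.44-fold higher (1.29, SE 0.13, adjusted p = 0.000165) and C8a was 1.99-fold higher (0.99, SE 0.13, adjusted p = 0.000737). The lower members were Hc, which encodes complement C5, at 2.36-fold (-1.24, SE 0.063, adjusted p = 4.0e-06), and C2, at 1.35-fold (-0.44, SE 0.059, adjusted p = 0.00104). The median difference was 0.28 (camera adjusted p = 0.000116, and adjusted p = 0.233 with an estimated correlation). Acute phase genes split, with 8 of 28 higher and 5 lower (12 and 8 adjusted over the list alone). Orm1 and Orm2 were 7.68-fold and 2.70-fold higher (2.94 and 1.43, SE 0.34 and 0.20). The lower ones were the transcription factor gene Cebpb (-1.34, SE 0.13, adjusted p = 0.000145), the interleukin receptor genes Il1r1 (-1.02, SE 0.14, adjusted p = 0.00113) and Il6ra, and the metallothionein genes Mt2 and Mt1. The list's shift did not pass (camera adjusted p = 0.182, and adjusted p = 0.478 with an estimated correlation), though it passed with the mean of a gene's probe sets (0.0312). Its share of called genes was raised (Fisher's exact test, adjusted p = 0.00576). Mt1 has another probe set that was higher in NZB, and its call ended without any array but NZB replicate 1 (adjusted p = 0.0557 to 0.165) and after quantile normalization (0.0704). Its difference was 0.11 with the mean of its probe sets (adjusted p = 0.552) and 0.52 without those marked for cross-hybridization (adjusted p = 0.0335). Il1r1 differed by -0.49 with the mean of its probe sets.

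Of 39 measured interferon response genes, 9 were higher in NZB, 1 was lower and 29 did not pass the test (9 and 1 adjusted over the list alone). The guanylate binding protein gene Gbp6 was 4.67-fold higher (2.22, SE 0.16, adjusted p = 3.6e-05), the chemokine gene Cxcl9 was 2.43-fold higher (1.28, SE 0.34, adjusted p = 0.0255), and Gbp3 was 1.37-fold lower (-0.46, SE 0.099, adjusted p = 0.0109). Of 24 measured genes of the major histocompatibility complex (MHC) and antigen presentation, 10 were higher, 3 were lower and 11 did not pass (11 and 3 adjusted over the list alone). The class II genes H2-Aa, at 2.65-fold (1.41, SE 0.21, adjusted p = 0.00188), and Cd74, at 2.62-fold (1.39, SE 0.20, adjusted p = 0.00152), differed most, and the class I genes H2-K1 (-0.55, SE 0.063, adjusted p = 0.00043), H2-Q10 (-0.43, SE 0.071, adjusted p = 0.00289) and H2-T24 were lower. H2 genes vary in sequence between strains and resemble one another, so these values are uncertain. In the same arrays, 8 of 13 B and plasma cell markers and 11 of 18 markers of Kupffer cells and macrophages were higher. B cells and macrophages carry class II proteins, and the first list does not separate B cells from plasma cells. The interferon list was shifted by a median of 0.11 (camera adjusted p = 0.0328, and adjusted p = 0.732 with an estimated correlation), and the MHC list, with a median of 0.12, missed the threshold (0.0677, and adjusted p = 0.478 with an estimated correlation). The MHC list's share of called genes was raised (Fisher's exact test, adjusted p = 0.00168). The interferon call ended without SM replicate 1 (0.822, median 0.013, 4 members lower) or NZB replicate 2 (0.0823, median 0.071, 2 members lower). Its median was 0.19 without SM replicate 2, 0.17 without SM replicate 3 and 0.19 without NZB replicate 1. Without SM replicate 2 and without NZB replicate 3, the higher members numbered 5 and 5 for interferon and 6 and 5 for MHC. The MHC list passed without NZB replicate 1 (camera, 0.0194) and under 4 other settings (0.00529 to 0.0494), with a median of 0.26 where dim probe sets were left out. Its raised share did not pass without SM replicate 3 (0.0920) or NZB replicate 3 (0.0603). Single arrays left out ended the calls of Cxcl9 (0.0616 to 0.0863 without SM replicate 2 or 3, with a difference of 0.83 without NZB replicate 3), Gbp3 (0.0508 without SM replicate 2) and H2-T24 (0.0681 to 0.118 without any array but SM replicate 1). The interferon call also ended with array weights (0.126) and the mean of a gene's probe sets (0.0706), and that of Cxcl9 with trended and robust variances (0.145). With the mean of their probe sets Cxcl9 differed by 0.77 and H2-Aa by 0.85.

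Among 13 measured B and plasma cell markers, 8 were higher in NZB livers and none was lower (10 adjusted over the list alone), led by Ighm and Jchain and with a median difference of 0.29. Of 18 measured markers of Kupffer cells, the resident macrophages of the liver, and of other macrophages, 11 were higher and 2 were lower, the same adjusted over the list alone, with a median of 0.35. Lysozyme, Lyz2, was 5.01-fold higher (2.32, SE 0.16, adjusted p = 2.2e-05) and Cd5l, a protein secreted by macrophages, was 1.68-fold higher (0.75, SE 0.092, adjusted p = 0.000618). The lower ones were the scavenger receptor gene Marco (-0.66, SE 0.14, adjusted p = 0.0102) and Spic (-0.32, SE 0.084, adjusted p = 0.0243). Of 15 T cell markers 6 were higher, of 11 NK cell markers 4, and of 12 markers of neutrophils and granulocyte precursors 3, with none lower in any of these lists (6, 5 and 4 adjusted over each list alone). Examples were Thy1 (0.40, SE 0.060, adjusted p = 0.00187) and Cd3g (0.34, SE 0.066, adjusted p = 0.00673) for T cells, Klrk1 (0.42, SE 0.098, adjusted p = 0.0158) and Ccl5 (0.34, SE 0.083, adjusted p = 0.0183) for NK cells, and S100a8 (1.00, SE 0.19, adjusted p = 0.00571) and S100a9 (0.51, SE 0.081, adjusted p = 0.00226) for neutrophils. Klrd1 and Nkg7 completed the higher NK markers and Ngp the neutrophil markers. Cd3g and Klrd1 read under background in both strains and Thy1 in SM. Some of the higher B and plasma cell markers also read under background in at least 1 strain. The camera adjusted p was 1.6e-05 for B and plasma cells, 0.000226 for macrophages, 0.0105 for T cells, 0.00963 for NK cells and 0.00419 for neutrophils. With an estimated correlation these were adjusted p = 0.233, 0.389, 0.260, 0.330 and 0.260. The share of called genes was not raised for T cells, NK cells or neutrophils (Fisher's exact test, adjusted p = 0.121, 0.273 and 0.571), though that of T cells passed with the mean of a gene's probe sets (0.0268). The higher T cell markers numbered 3 without SM replicate 2, NZB replicate 1 or NZB replicate 2. The NK markers numbered 1, 0, 2 and 0 without SM replicate 1, SM replicate 2, NZB replicate 2 and NZB replicate 3, the macrophage markers 7 without NZB replicate 2, and the NK median was 0.24 without NZB replicate 1. The calls of Klrk1 (0.0667 to 0.0669 without SM replicate 2 or NZB replicate 3), Ccl5 (0.0526 to 0.0751 without SM replicate 1 or 2 or NZB replicate 3), Klrd1 (0.0767 to 0.1003 without SM replicate 1 or 2 or NZB replicate 2 or 3), Nkg7 (0.0521 to 0.124 without any array but SM replicate 3) and Spic (0.0558 to 0.0847 without SM replicate 2 or any 1 NZB array) ended with 1 array left out. With dim probe sets left out, 3 B cell and 2 T cell markers were higher and the T cell list was no longer called (0.0788), and with array weights 5 neutrophil markers were higher. The call of Nkg7 also ended with medians aligned (0.0557) and after quantile normalization (0.0602).

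The circadian clock genes differed in 15 of 18 cases, 11 lower and 4 higher in NZB (12 and 6 adjusted over the list alone). Dbp, an output gene of the clock, was 5.29-fold lower (-2.40, SE 0.44, adjusted p = 0.00506), at 11.3, 11.5 and 11.6 in the SM arrays and 7.92, 10.2 and 9.11 in the NZB arrays. The deubiquitinase gene Usp2 was 3.73-fold lower (-1.90, SE 0.18, adjusted p = 0.000145). The higher ones were Arntl, which encodes the core clock activator BMAL1, at 2.23-fold (1.16, SE 0.20, adjusted p = 0.00389), Nfil3 at 2.10-fold (1.07, SE 0.19, adjusted p = 0.00361), Clock and Npas2. The list's median difference was -0.62 (camera adjusted p = 0.00191, and adjusted p = 0.260 with an estimated correlation), and its share of called genes was raised (Fisher's exact test, adjusted p = 1.1e-06). The call of Npas2 ended without SM replicate 2 or 3 or NZB replicate 1 or 3 (adjusted p = 0.0654 to 0.133, with a difference of 0.21 without NZB replicate 1) or with medians aligned (0.0844) or quantile normalization (0.0963), that of Clock with the mean of its probe sets (0.0514) and that of Dbp with trended and robust variances (0.0736, range over all settings 0.000395 to 0.0736). Arntl differed by 0.69 with the mean of its probe sets.

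Heat shock genes were lower in NZB in 8 of 12 cases with none higher (8 lower and 1 higher adjusted over the list alone), with a median difference of -0.42. The chaperone genes Hsph1 (-1.04, SE 0.15, adjusted p = 0.0013) and Hspa4l (-1.03, SE 0.12, adjusted p = 0.000429) were 2.05-fold and 2.04-fold lower. Of 23 measured proliferation genes, 11 were higher, 1 was lower and 11 did not pass (14 and 1 adjusted over the list alone), with a median of 0.28. The cell cycle marker Mki67 was higher (0.75, SE 0.079, adjusted p = 0.000261), at 5.86 ± 0.14 in NZB and under background at 5.12 in SM, the replication gene Mcm6 was 1.61-fold higher (0.68, SE 0.13, adjusted p = 0.00529), and Pcna, the sliding clamp of replication, was 1.24-fold lower (-0.31, SE 0.081, adjusted p = 0.0255). Birc5, Aurkb and Ttk, also among the higher genes, read under background in SM as well. Against background they were at least 1.37-fold, 1.15-fold and 1.12-fold higher, and Mki67 at least 1.14-fold. In the same arrays, 8 of 13 B and plasma cell markers and 11 of 18 macrophage markers were higher. Both the heat shock and the proliferation list were shifted (camera adjusted p = 0.00078 and 6.8e-05, and adjusted p = 0.260 and 0.330 with an estimated correlation). Of 19 immediate early genes, Egr1 was 4.01-fold higher (2.00, SE 0.28, adjusted p = 0.00121), Gadd45g was 2.03-fold higher (1.02, SE 0.23, adjusted p = 0.0136) and Atf3 was higher. Both Btg2 (-0.30, SE 0.084, adjusted p = 0.0327) and Jund (-0.21, SE 0.064, adjusted p = 0.0429) were lower. Of 16 genes of endoplasmic reticulum (ER) stress, Sdf2l1 was higher (1.11, SE 0.12, adjusted p = 0.00028). Lower were Herpud1 (-1.35, SE 0.11, adjusted p = 6.9e-05), Dnajb9 (-0.38, SE 0.070, adjusted p = 0.0052) and Dnajc3, though another probe set of Dnajc3 was higher and the mean of its probe sets did not pass (0.709). With the mean of a gene's probe sets 5 ER stress genes were higher and 3 lower, and their share of called genes was raised (Fisher's exact test, adjusted p = 0.0109, against 0.547). Neither of these lists was shifted (camera adjusted p = 0.284 and 0.697, and adjusted p = 0.579 and 0.871 with an estimated correlation). The share of called genes was not raised for the immediate early genes (Fisher's exact test, adjusted p = 0.488). Adjusted over the list alone, 3 were higher and 2 lower for the first and 2 and 3 for the second. The lower heat shock genes numbered 5 without SM replicate 2, and 1 heat shock gene was higher without NZB replicate 2. The higher proliferation genes numbered 7, 6 and 7 without SM replicate 2, NZB replicate 2 and NZB replicate 3, and 4 with dim probe sets left out. The calls of Pcna (0.0510 to 0.0818 without SM replicate 1 or 2 or NZB replicate 1 or 3), Btg2 (0.0783 to 0.119 without SM replicate 2 or 3 or NZB replicate 1 or 3), Jund (0.0774 to 0.145 without any array but SM replicate 1) and Atf3 (0.0704 to 0.105 without SM replicate 1 or 3 or NZB replicate 2 or 3) ended with 1 array left out. Other settings also ended those of Pcna (0.0808 in 1 setting), Btg2 (0.0646 in 1), Jund (0.258 to 0.376 in 2) and Atf3 (0.0570 to 0.0664 in 2). Besides these, the replicate block ended the calls of Pcna, Btg2 and Jund (limma adjusted p = 0.0565, 0.0521 and 0.0783). With the mean of their probe sets Mcm6 differed by 0.41 and Btg2 by -0.56. That of Gadd45g ended with trended and robust variances (0.0787, range over all settings 0.00624 to 0.0787).

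**Figure D3:**
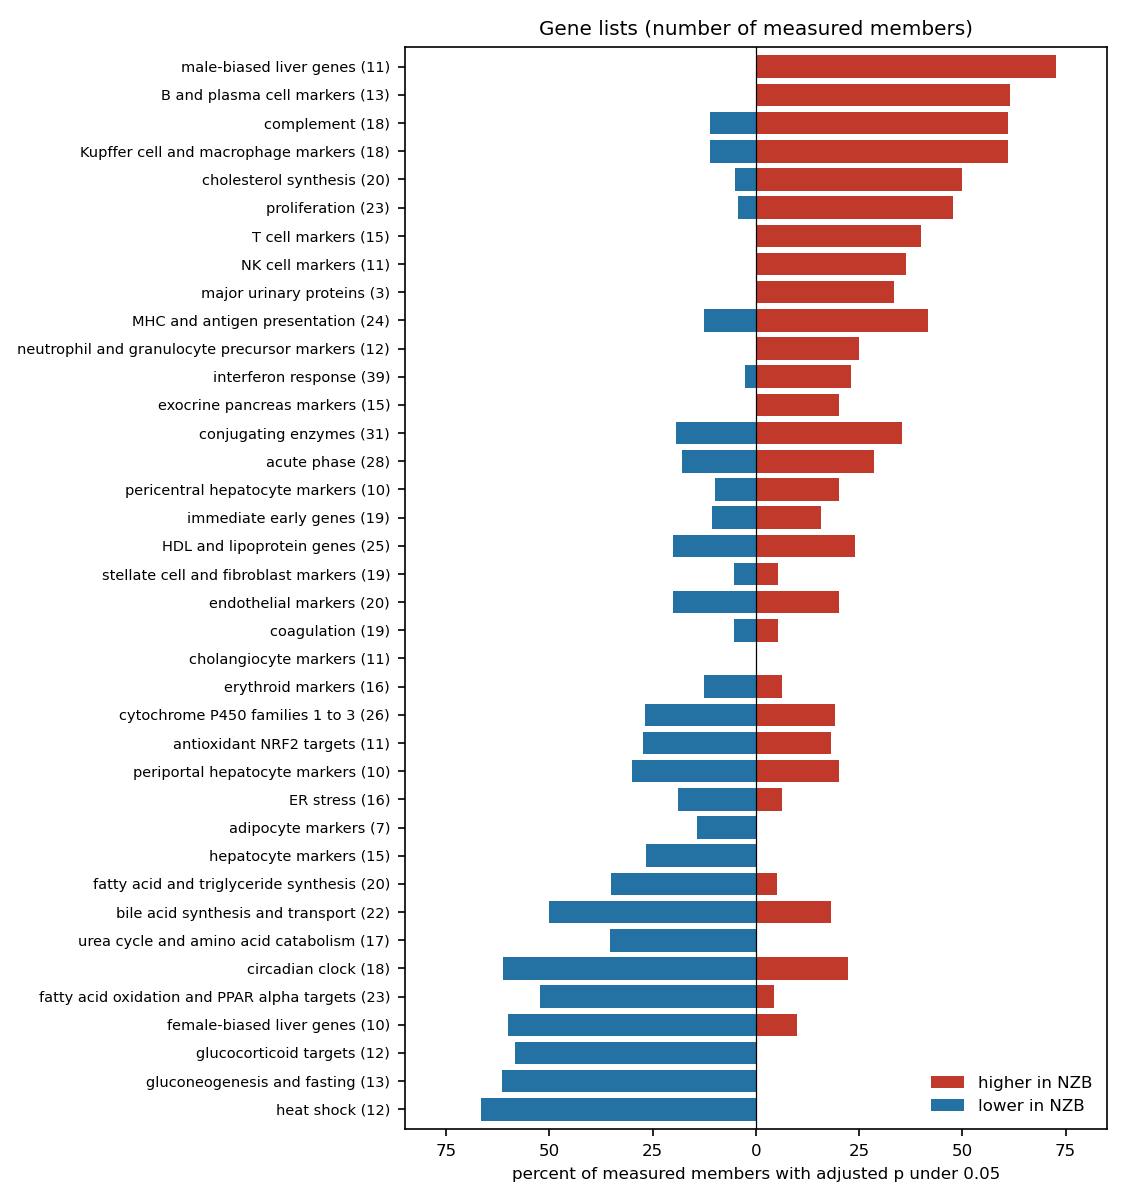
Bars give the percent of each gene list's measured members (their number in brackets) with a limma adjusted p under 0.05, to the right where they were higher in NZB and to the left where they were lower. Male-biased genes (8 of 11 higher) lie at the top, and gluconeogenesis (8 of 13 lower) and heat shock genes (8 of 12 lower) at the bottom.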

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

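All alternatives in this part were planned, and the 32 genes named to complete small counts were chosen after their values were seen. Of 141 named genes past the threshold, 100 stayed past it without any 1 array, 41 lost the call without at least 1 array and 38 lost it under another setting. Without 1 array the genes differing numbered 2371 to 3847, of which 873 to 1445 were higher and 1498 to 2402 lower in NZB, and the probe sets numbered 3741 to 6386. The low ends came without SM replicate 2 or NZB replicate 3, and fewer samples are part of that change. Of the 3827 genes called with all arrays, 2324 were called without SM replicate 2 and 2334 without NZB replicate 3. Genes differing at least 2-fold numbered 268 to 289 and lists shifted 18 to 22. Under the other settings the genes differing numbered 3382 to 4366, and 3273 of the 3827 stayed called with the replicate block, 3706 with trended and robust variances, 3408 with medians aligned, 3039 after quantile normalization and 3776 with array weights. With the mean of a gene's probe sets 2867 stayed called and 55 of the 3827 changed sign, and without probe sets marked for cross-hybridization 3585 of 3766 stayed called and 51 changed sign. Lists shifted numbered 0 with the estimated correlation and 16 with dim probe sets left out. Lists with a raised share of called genes fell from 18 to 13 with dim probe sets left out. Mt1 turned from a log2 difference of -0.31 to 0.11 with the mean of its probe sets (adjusted p = 0.552) and to 0.52 without probe sets marked for cross-hybridization (adjusted p = 0.0335), where its other probe set counts more or alone. Abca1 passed the threshold in 4 settings (lowest adjusted p = 0.0439, highest 0.641). For the other changed calls the cause was not tested. The equal replicate numbers do not pair the mice, since deviations of same-numbered arrays correlated at 0.0373, -0.0545 and 0.0249, and not every array correlated best with its own number. The replicate block gave 3436 genes. With it Angptl4, Btg2, Cyp2c50, Fabp1, Fcgr2b, Jund and Pcna did not pass (limma adjusted p = 0.0521 to 0.0814), and the share of called genes passed for the NRF2 targets (Fisher's exact test, adjusted p = 0.0179), fatty acid and triglyceride synthesis (0.0430) and periportal markers (0.0457). The offset planned for linear values was not run, because the values are on a log scale. Differences near background are compressed, and of the called genes 118 read at or under 5.67, the highest Y-linked reading, in both strains and 101 in 1 strain.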

Other observations

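The tests of fewer hepatocytes, time of day, a failed probe set and a male mouse were chosen after the result was seen. Of 15 hepatocyte markers 4 were lower in NZB and none was higher (the same adjusted over the list alone), namely Asgr2, a subunit of the asialoglycoprotein receptor (-0.56, SE 0.076, limma adjusted p = 0.00112), the liver transcription factor Hnf4a (-0.38, SE 0.084, adjusted p = 0.0113), Arg1 and Cebpa. The list's median was -0.14 (camera adjusted p = 0.0457, and adjusted p = 0.276 with an estimated correlation), and its call ended without SM replicate 2, SM replicate 3 or NZB replicate 3 (0.0554 to 0.0908), without dim probe sets (0.180) and without probe sets marked for cross-hybridization (0.0532). Its share of called genes was not raised (Fisher's exact test, adjusted p = 0.499). The call of Arg1 ended without SM replicate 2 (0.0566) and that of Cebpa without SM replicate 1 or 3 or NZB replicate 1 or 2 (0.0587 to 0.0988). Of 10 pericentral genes, the stem cell marker Lgr5 (0.52, SE 0.13, adjusted p = 0.0237) and Lect2 (0.34, SE 0.072, adjusted p = 0.00924) were higher and the glutamate transporter gene Slc1a2 (-0.98, SE 0.092, adjusted p = 0.00014) was lower (3 and 1 adjusted over the list alone). The call of Slc1a2 ended with the mean of its probe sets (-0.13, adjusted p = 0.198), as did those of Hnf4a (-0.25, 0.136), Hsd17b13 (-0.087, 0.316) and Etnppl (0.94, 0.121). Lgr5 differed by 0.25 with the mean of its probe sets. Of 10 periportal genes, Ctsc (0.84, SE 0.089, adjusted p = 0.000278) and Etnppl (0.75, SE 0.20, adjusted p = 0.0271) were higher and Pck1 (-0.41, SE 0.10, adjusted p = 0.0193), Hsd17b13 (-0.36, SE 0.079, adjusted p = 0.0115) and Arg1 were lower (3 and 3 adjusted over the list alone). Neither zone was shifted (camera adjusted p = 0.588 and 0.697, and adjusted p = 0.809 and 0.879 with an estimated correlation), and the periportal median of -0.092 and mean of 0.027 differ in sign. Without SM replicate 2 the counts were 1 higher pericentral, 1 higher periportal and 1 lower periportal gene, without NZB replicate 1 and without NZB replicate 3 the higher genes numbered 1 in each zone, and without SM replicate 3 there were 2 lower pericentral genes. Single arrays left out ended the calls of Lgr5 (0.0564 to 0.0946 without SM replicate 1 or 2 or NZB replicate 1 or 3), Etnppl (0.0646 to 0.106 without SM replicate 2 or NZB replicate 1 or 3, and 0.107 with trended and robust variances) and Pck1 (0.0507 to 0.0755 without SM replicate 1 or 2 or NZB replicate 2).

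Of 20 endothelial markers, Stab2 (0.97, SE 0.14, limma adjusted p = 0.00168), Pecam1 (0.34, SE 0.064, adjusted p = 0.00571), Gpr182 and Fcgr2b were higher in NZB and Lyve1 (-0.65, SE 0.081, adjusted p = 0.000647), Bmp2 (-0.59, SE 0.094, adjusted p = 0.00234), Vwf and Clec4g were lower, the same adjusted over the list alone. Of 16 erythroid markers, Car1 (0.37, SE 0.095, adjusted p = 0.0226) was higher and Alas2, the first enzyme of erythroid heme synthesis (-1.09, SE 0.26, adjusted p = 0.0151), and Klf1 (-0.73, SE 0.14, adjusted p = 0.00618) were lower, the same adjusted over the list alone. Of 15 exocrine pancreas markers, Cela1 (0.64, SE 0.14, adjusted p = 0.0111), Cela2a (0.28, SE 0.075, adjusted p = 0.0262) and Cel were higher, also the same. Of 19 stellate cell and fibroblast markers Vim was higher and Ecm1 lower, and of 19 coagulation genes F11 was higher and F12 lower, both the same adjusted over the list alone. With trended and robust variances, and with the mean of a gene's probe sets, 4 coagulation genes were higher (2 with dim probe sets left out), and with array weights 3 stellate markers were. With the mean of its probe sets Lyve1 differed by -1.46, and its other probe set by -2.27. Of 7 adipocyte markers Lipe was lower (2 adjusted over the list alone, with dim probe sets left out or with array weights). None of 11 cholangiocyte markers passed the limma test, and 2 had an unadjusted p under 0.05. Without SM replicate 2, SM replicate 3 or NZB replicate 1, 1 of them was lower. The camera adjusted p ranged from 0.0511 for pancreas to 0.965 for endothelial and adipocyte markers, and adjusted p = 0.478 to 0.971 with an estimated correlation. Median and mean differ in sign for the endothelial (0.028 and -0.00068), erythroid (0.067 and -0.038), stellate (-0.016 and 0.010) and adipocyte markers (0.047 and -0.039). The pancreas list passed without SM replicate 3 (0.0228) and without NZB replicate 1 (0.0205), with medians aligned (0.0483) and with array weights (0.0461), and 1 of its markers was higher without SM replicate 2 and with dim probe sets left out. Higher endothelial markers numbered 2 without SM replicate 2, SM replicate 3 or NZB replicate 1 and with medians aligned, and 4 stellate markers were higher without SM replicate 1 and 2 lower without NZB replicate 1. Single arrays left out ended the calls of Alas2 (0.0506 to 0.0595), Car1 (0.0512 to 0.0899), Gpr182 (0.0558 to 0.0876), Fcgr2b (0.0511 to 0.0926), Cela2a (0.0578 to 0.0983), Cel (0.0663 to 0.0689), Vim (0.0806 to 0.110), F12 (0.0548 to 0.0739) and Lipe (0.0553 to 0.0834). Those arrays were NZB replicates 1 and 3 for Alas2, SM replicates 2 and 3 with NZB replicates 1 and 2 for Car1 and Cela2a, and SM replicates 2 and 3 with NZB replicate 1 for Gpr182. They were any but NZB replicate 3 for Fcgr2b, SM replicate 2 and NZB replicate 3 for Cel, these and NZB replicate 1 for Vim, these 3 and SM replicate 3 for Lipe, and NZB replicates 2 and 3 for F12. Other settings ended the calls of Alas2 (0.0955), Clec4g (-0.16, 0.0860), Lipe (-0.14, 0.124), Gpr182 (0.0505), Fcgr2b (0.0579 to 0.0612) and Cela2a (0.0510 to 0.0574).

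Of 11 male-biased genes 8 were higher in NZB females, and of 10 female-biased genes 6 were lower and 1, Hao2, was higher. Neither list's shift passed with an estimated correlation (camera, adjusted p = 0.330 for both). If the NZB arrays came from males, Xist would lie at least 2 log2 lower in NZB. Xist differed by 1.61 (SE 1.22) in the other direction, the 3 NZB arrays read 12.6 to 12.7, and the Y-linked genes differed by a median of 0.0298, which argues against males. Of the Y-linked genes Uty passed the limma test (0.25, adjusted p = 0.0297), at 4.61 in SM and 4.86 in NZB, under the background reading of 5.67. The bound written for the opposite outcome, Xist within 1 log2, was not met because of the low Xist of SM replicate 2, so the verdict rests on the NZB readings. A lower share of hepatocytes in NZB would lower the male-biased genes too, but their median was 1.03 (SE 0.369). It therefore cannot by itself explain the rise of these genes. That rise was part of the pattern already seen, so it is no independent test, and a part in the lower female-biased genes stays open. Without NZB replicate 3 the median was 0.574 (SE 0.338), above 0 by less than the margin set for that test. The SE is taken across the 11 genes and measures no spread between mice. These genes are not independent (estimated correlation 0.51), so it is too narrow. A strain difference in the hormonal control of these genes stays open as a hypothesis, and no hormone was measured.

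Clock genes differed between the strains in both directions. Unequal scaling of the arrays would move the list's median to near 0 after quantile normalization, and the median was -0.556. The deposited values were already normalized, and this step moved the median difference of all genes by only -0.0032. The check therefore had little room to come out otherwise. The 4 genes that peak near the end of night had a median of 0.769 and the 7 that peak near the end of day a median of -1.52, a gap of 2.29. These genes had already been seen to differ, so the gap restates the pattern and tests no explanation. A different time of day at dissection and a strain difference in the clock cannot be told apart, since each predicts such a gap and the labels give no dissection times. The same limit holds for any gene of the other lists whose level follows the time of day, and which genes do was not analysed here.

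SM replicate 2 had low Xist. A single failed probe set is excluded, since 3 Xist probe sets read lower by a median of -5.56 (-5.69 to -3.69) against SM replicates 1 and 3. A male mouse would have Y-linked RNA, but 9 probe sets of 3 Y-linked genes differed by a median of 0.0046 and read at most 5.67 in any array. A candidate explanation is a mouse, or liver cells, with a single X chromosome. Genes that escape X inactivation (Kdm6a, Kdm5c, Eif2s3x, Ddx3x and Pbdc1) would then be lower, and their median was -0.211, at the 0.07 percentile of 10000 random X-linked lists of that size. Those lists drew on X-linked genes of any level, dim ones included, so the percentile may be too extreme. Kdm5c differed by only -0.050. In SM replicate 2, Kdm5c (8.137) and Ddx3x (11.78) read no lower than the NZB means (8.136 and 11.76), while Kdm6a, Eif2s3x and Pbdc1 read lower than theirs. All 616 X-linked genes had a median of -0.0109 and all genes one of -0.0141. This is a hypothesis found and tested on the same array, and no DNA was measured.

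The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. In each of the following counts 1 split, the real one, gave a count as large. The real split gave 3827 genes, 6659 probe sets, 280 genes with at least 2-fold difference, 20 shifted lists and 18 lists with a raised share of called genes. The highest of the other splits by limma, camera and Fisher's test gave 0, 0, 0, 14 and 0. At an unadjusted p under 0.05, the real split gave 6272 genes, 13184 probe sets and 21 lists with a raised share, and the highest other counts were 1024, 2607 and 0. Every other split puts mice of both strains in each group, so strain differences enter its spread within groups. The counts of the other splits are therefore not those to be had without a strain difference.

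A hypothesis was tested that called genes lie next to each other, as inherited segments that differ between strains could produce. Of 18008 adjacent gene pairs, 577 were called in the same direction, against a mean of 416.6 and a highest value of 484 in shuffled gene orders (permutation test, p = 1e-04, the smallest that 10000 shuffles can give). Probe sets that read related neighbours could raise this count, but without pairs whose symbols share 3 letters it was 505 of 16520, against a mean of 382.2 and a highest value of 447 (permutation test, p = 1e-04, again the smallest possible). Pairs called in opposite directions numbered 380 against a mean of 385.8 (permutation test, p = 0.64). The excess of pairs in the same direction is consistent with differences shared by neighbouring genes. Sequence variants under the probes, which would also cluster in such segments, were not analysed here and stay open.

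After its values were seen, the immunoglobulin pattern was also looked at through 10 genes of antibody-making cells, of which 6 were higher in NZB by limma, some of them near background, and no explanation was weighed for it.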
